A study of Mus musculus with 33 samples.

How the data were processed

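Bulk RNA-seq was measured in 33 libraries of mouse pancreatic acinar cells, the cells that make digestive enzymes. Per the labels' protocols, cells marked with the red fluorescent protein tdTomato were isolated by fluorescence-activated sorting into Trizol, total RNA was extracted with phenol-chloroform, and libraries were prepared with a TruSeq kit that selects poly-A RNA and does not keep the strand. The same protocols give paired-end sequencing on an Illumina HiSeq or NovaSeq instrument, without stating which library ran on which instrument. The deposited values are whole-number counts of read pairs per gene, made with featureCounts 1.6.2 in paired-end mode, per the file headers. Those headers record that reads were summarised by gene name on a GENCODE mouse annotation, with no option for strand and none for reads that match several places, and the 7 files of the CP set give another annotation path than the other 26. The submitters' processing notes name the mm9 mouse genome build, STAR, FastQC, featureCounts and limma, with no role or version. No other normalization or filtering by the authors is recorded in the sources used here. Gene positions were taken from the files, which are on mm9, and the coordinates of a later mouse build were not used.

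Each file held 33924 genes, and all 33 files were used. Libraries were grouped by the labels for genotype, caerulein or saline, and recovery time, within 3 sets named by the first word of the sample titles (CP, MD4 and INV3), which gave 11 groups. What the set names stand for is not stated, nor is a 2D or 2d part in the titles of all INV3 libraries, whose labels give 12 weeks. Single libraries of INV3 and the CP 2-day group are named by the last part of their titles (such as mtS-1662 or C2D_555). The sets were fitted apart, because the labels give no control shared between them. Total counts per library ranged from 31179178 to 55637363 in the CP set (7 libraries), from 26912880 to 40475080 in MD4 (14 libraries) and from 28088700 to 39978311 in INV3 (12 libraries). Within groups, the counts of 35 pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 6.85 to 245 over genes with at least 20 counts, so every library was kept as its own sample. The labels do not state that every library came from a separate animal, so p-values may measure only the spread between these samples. Intervals and floors cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules.

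Differential expression was tested in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood F test with robust estimation, on counts scaled by TMM factors. Genes were kept by edgeR's expression filter per group (a minimum count of 10 and a minimum total of 15), each set had 1 dispersion estimate over all its libraries, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and standard errors (SE) of log2 fold changes were taken from the F statistic. Of the 12 comparisons, 1 joined the wild-type libraries of MD4 and INV3 at 12 weeks, with the set as a covariate. Levels are given as CPM, the usual depth-scaled count, on TMM-scaled library sizes. A fold against a group with no counts was computed against a floor of 3 counts over that group, and ratios with 1 to 3 counts in a group carry 95% counting intervals. Because the counting used no strand, reads of overlapping or antisense genes were not separated, and near-identical paralogs (trypsinogens, amylases, Reg genes, globins) may share reads.

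The gene lists, the design, the alternative settings and the rule for naming genes were fixed before the data were examined. The 23 lists held 419 symbols, of which 412 were in the files. They were acinar digestive enzymes, acinar transcription factors, ductal and metaplasia markers, progenitor and injury transcription factors, AP-1 factors, immediate early and dissociation stress genes, gastric, mucous and tuft genes, Reg, acute phase and NF-kB targets, interferon and antigen presentation, unfolded protein and integrated stress response, cell cycle, ERK pathway output, epithelial wound and matrix genes, cholesterol and lipid synthesis, oxidative phosphorylation, sex-linked genes, and markers of macrophages, lymphocytes, fibroblasts, endothelium, islets, adipocytes and erythroid cells. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry stood beside it. In each comparison, the named genes were called genes whose lowest library in the higher group lay above the highest library in the lower group, with a mean of at least 10 CPM in the higher group and no predicted or unnamed symbol. From these, the 10 largest rises and the 10 largest falls were taken (5 and 5 in the CP comparisons, the interactions and the saline time comparison). Up to 4 members of each list with the lowest adjusted p, and Kras, Ptf1a, Cpa1, Krt19, Sox9, Clu, Reg3b, Onecut2 and Fosl1, were added by the same rule. Other genes are said to be chosen after their values were seen.

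Genes called at 2 days in MD4 with at least 2-fold change formed an up set and a down set, which were tested with camera in later comparisons that share no library with them. Alternative settings were DESeq2 1.42.0, limma-voom, RLE size factors, no expression filter, a filter at 5 CPM, leaving out the enzyme list, fitting only the groups compared, a replicate block, leaving out each library in turn, an estimated inter-gene correlation, fry, a covariate for the number in INV3 titles (under 1700 or not), and other definitions of the 2-day sets, one of them the 200 genes with the lowest p per direction. Total-count scaling and a covariate for the sex of the animals (XX or XY, read from Xist and Y-linked genes because the labels give no sex) were added after the data were seen. The procedure was tested on simulated counts with known changes. At 2 days in MD4, 53.3% of genes changed by 2-fold were recovered and 97.8% of those by 4-fold, with 9 of 145 calls false. At 12 weeks in MD4 recovery was 71.9% and 97.8% (9 of 161 false). In the INV3 interaction it was 37.8% and 78.8% (9 of 124 false). At 2 days in CP it was 24.1% and 84.3% (13 of 108 false). For KrasG12D caerulein 14 of 167 were false. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.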

Results

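Poly-A RNA was sequenced from sorted mouse acinar cells to ask what an episode of pancreatitis leaves behind in them, with and without the oncogene KrasG12D. Pancreatitis was induced with caerulein, a peptide that overstimulates acinar secretion, and animals were left to recover for 2 days, 3 weeks or 12 weeks. The MD4 set held wild-type (WT) libraries after saline or caerulein, with 3 of each at 2 days and 4 of each at 12 weeks. The CP set held 2 naive WT libraries, 2 at 2 days after caerulein and 3 at 3 weeks. The INV3 set, with 12 weeks of recovery by its labels, held 3 libraries each of WT saline, WT caerulein, KrasG12D saline and KrasG12D caerulein. Its titles also hold a 2D or 2d part whose meaning is not stated, so every 12-week value of INV3 rests on the label. Total counts ranged from 26912880 to 55637363 per library.

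Digestive enzyme genes took a large share of the counts, and that share fell 2 days after caerulein. The 27 listed enzyme genes made up 75.0% ± 0.279 (SD, n = 3) of counts in MD4 saline libraries at 2 days and 55.2% ± 2.40 (n = 3) after caerulein. At 12 weeks the shares were 77.2% ± 1.10 (n = 4) with saline and 78.5% ± 1.40 (n = 4) with caerulein. In the CP set the share was 73.9% ± 3.00 (n = 2) in naive libraries, 27.3% ± 2.65 (n = 2) at 2 days and 70.8% ± 3.24 (n = 3) at 3 weeks. In INV3 the group means lay between 76.3% and 77.4%. TMM scaling centres on the bulk of genes, and without it the median log2 fold change of all genes moved by 1.64 in the MD4 2-day comparison, by 2.57 in the CP 2-day comparison, by 0.30 in the CP 3-week comparison and by -1.62 in the MD4 comparison of both times. It moved by -0.11 between the MD4 saline groups, 0.20 for caerulein in KrasG12D libraries, 0.11 for genotype after caerulein and 0.12 in the INV3 interaction. All other changes are given relative to the TMM scale.

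**Figure D1:**
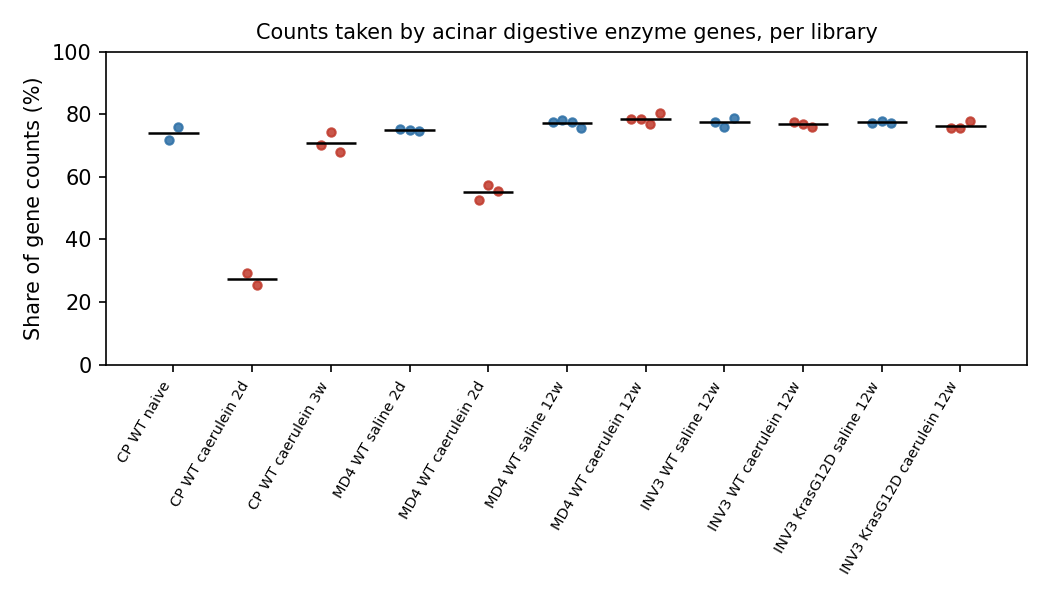
Share of gene counts (%) taken by the listed acinar digestive enzyme genes in each library (points; red, caerulein; blue, saline or naive; bars, group means). The mean fell to 27.3% in CP and 55.2% in MD4 libraries 2 days after caerulein and lay between 70.8% and 78.5% in the other 9 groups.

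The first comparison asked what acinar cells expressed 2 days after caerulein. Secretory genes fell and cell cycle, gastric and matrix genes rose in the MD4 libraries, though the cell cycle and matrix lists did not pass camera with an estimated correlation (adjusted p = 0.0911 for both) and fibroblast markers rose with them. Pnlip (mm9 chromosome 19, 58744855 to 58756276, plus strand), which encodes pancreatic lipase, fell by 4.32 on the log2 scale (SE 0.322, adjusted p = 8.32e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Cpa1, a carboxypeptidase, fell by 2.31 (SE 0.173). Gal, a neuropeptide gene (mm9 chromosome 19, 3409919 to 3414472, minus strand), went from 74.8 ± 10.3 to 0.737 ± 0.401 CPM (SD, n = 3 each), the largest fall under the naming rule (log2 -6.67, SE 0.518). Mki67, a marker of proliferating cells (mm9 chromosome 7, 142881471 to 142908062, minus strand), went from 0.171 ± 0.139 to 34.7 ± 3.24 CPM (log2 7.70, SE 0.902, adjusted p = 5.11e-05). Gkn3 and Pgc, genes of stomach epithelium that encode a gastrokine and pepsinogen C, had no counts in the 3 saline libraries and reached 20.2 ± 8.01 and 14.6 ± 13.8 CPM after caerulein, at least 553-fold and at least 409-fold higher.

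Of 12589 genes tested, 4414 passed an adjusted p of 0.05 (edgeR), 2184 higher and 2230 lower, and 1397 rose and 787 fell by at least 2-fold. With total-count scaling the split was 11536 higher and 137 lower. Other large rises were cell division genes, with log2 changes of 7.82 for Ccna2, 6.73 for Top2a, 6.67 for Uhrf1, 6.60 for Cdc20, 6.40 for Ube2c and 6.21 for Racgap1. Ctse, a gastric protease, had 2 counts in the saline libraries and 16.6 ± 2.68 CPM after caerulein, a ratio with a 95% counting interval of 185 to 5513. Other large falls were Fxyd1 (log2 -5.49), Dusp26 (-4.68), Itih4 (-4.62), Hamp2 (-4.54), Galnt6 (-4.13), Padi2 (-4.10), Vtn (-3.85) and Lcat (-3.77), with adjusted p-values (edgeR) from 1.49e-09 to 1.42e-05. Pgc had an adjusted p of 0.00715 in the fit of all 14 MD4 libraries and 0.0792 in the edgeR fit of the compared groups alone.

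Of 27 measured enzyme genes, 25 fell and 2 rose, the same counts when adjusted over the list alone (camera adjusted p = 8.31e-45, adjusted p = 0.0163 with an estimated correlation). Cela2a (log2 -2.96), Sycn (-3.58) and Amy2b (-3.10) were among the falls. The rises were Prss1 (log2 5.20, SE 0.675) and Prss3 (2.39, SE 0.464), trypsinogen genes whose reads the counting may share with near-identical copies. Acinar transcription factors went both ways, with 1 rise and 5 falls among 12, also when adjusted over the list alone (camera adjusted p = 0.116). Ptf1a, which maintains acinar identity, went from 30.4 ± 7.11 to 13.5 ± 1.86 CPM (log2 -1.17, SE 0.200, edgeR adjusted p = 0.000231), and Xbp1 changed by -1.07 (SE 0.157). With total-count scaling both turned positive, at 0.42 and 0.53. Of 20 oxidative phosphorylation genes 8 fell (8 when adjusted over the list alone, camera adjusted p = 0.00408, adjusted p = 0.628 with an estimated correlation). One was Ndufa1 (log2 -1.28), which turned to 0.32 with total-count scaling. Among 22 ductal markers 9 rose and 1 fell (10 and 1 when adjusted over the list alone, camera adjusted p = 0.00274, adjusted p = 0.136 with an estimated correlation). Their log2 changes were 2.61 for the keratin Krt7, 4.04 for Tspan8 and -1.32 for Muc1, the last 0.27 with total-count scaling. Krt19 (0.39), Sox9 (0.24) and Clu (0.35) did not pass, with adjusted p-values (edgeR) of 0.165, 0.499 and 0.113. Neither did Onecut2 (1.91, 0.0706), Reg3b (-1.42, 0.193) or Kras (-0.05, 0.844), whose log2 change was 1.56 with total-count scaling. Fosl1, an AP-1 subunit, was too low to be tested, at 0.181 ± 0.131 CPM against no counts, at least 5.04-fold higher.

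All 24 cell cycle genes rose, also when adjusted over the list alone (camera adjusted p = 6.52e-22, adjusted p = 0.0911 with an estimated correlation). Gastric, mucous and tuft genes rose in 8 of 12 and fell in 1, also when adjusted over the list alone (median log2 3.67, also with genes at 0 set to their bound, camera adjusted p = 1.03e-10, adjusted p = 0.00550 with an estimated correlation). Anxa10 was at least 208-fold higher, Cldn18 had 2 saline counts and a ratio with an interval of 103 to 3074. The gene that fell was Tff2, a secreted trefoil peptide (2024 ± 121 to 297 ± 58.7 CPM, log2 -2.77). Epithelial wound and matrix genes rose in 16 of 20 (17 when adjusted over the list alone, camera adjusted p = 2.94e-09, adjusted p = 0.0911 with an estimated correlation). They included S100a11 (log2 2.64), the adhesion receptor Cd44 (3.53) and Timp1, a protease inhibitor with 1 saline count and a ratio interval of 30.7 to 6795. Progenitor and injury factors rose in 8 of 20 and fell in 1 (9 and 1 when adjusted over the list alone, camera adjusted p = 0.00976, adjusted p = 0.0991 with an estimated correlation), with Id3 at 5.07 and Runx1 at 3.13. Targets of the kinase ERK rose in 7 of 16, also when adjusted over the list alone (camera adjusted p = 0.00307, adjusted p = 0.136 with an estimated correlation), led by the phosphatase gene Dusp4 (log2 4.90) and Phlda1 (2.39). Fibroblast markers rose with these lists, 11 of 13 (12 and 1 fall when adjusted over the list alone, camera adjusted p = 2.10e-07, adjusted p = 0.122 with an estimated correlation). Their summed level was 56.6 ± 13.2 CPM against 9.61 ± 6.77 with saline.

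The remaining lists did not pass camera at 2 days with all libraries. Genes of the unfolded protein response rose in 11 and fell in 3 of 22 (12 and 5 when adjusted over the list alone, camera adjusted p = 0.225), with the chaperone Calr at log2 1.11 and Pdia3 at 1.14. Cholesterol and lipid genes rose in 7 of 19 (9, with 1 fall, when adjusted over the list alone, camera adjusted p = 0.0567), with Dhcr7 at 1.41 and Fasn at 1.16. Immediate early genes rose in 6 and fell in 3 of 17 (the same when adjusted over the list alone, camera adjusted p = 0.0962), with Cyr61 at 2.20 and Ier5 at 2.18. Of the AP-1 genes 1 rose, Fosl2 (1.76, camera adjusted p = 0.484). Interferon genes rose in 4 of 22 (camera adjusted p = 0.0567), such as Oas1a (2.60). Reg and NF-kB genes rose in 5 and fell in 4 of 19 (6 and 4 when adjusted over the list alone, camera adjusted p = 0.942), with Icam1 at 2.56 and Reg3d at -1.84. Markers of macrophages rose in 1 and fell in 1 of 14 (camera adjusted p = 0.163, C1qa -2.74), and those of lymphocytes rose in 1 of 5 (camera adjusted p = 0.225, Trbc2 2.88). Endothelial markers rose in 3 of 10 (camera adjusted p = 0.333; Esam 2.18) and islet markers fell in 1 of 13 (camera adjusted p = 0.939; Pcsk1 -1.93). No sex-linked gene passed edgeR (camera adjusted p = 0.942). Single libraries decided 4 of these lists, which passed camera upward when 1 was left out: interferon without saline replicate 1 (0.00303) or caerulein replicate 1 (0.0417), cholesterol without saline replicate 3 (0.0114) or caerulein replicate 1 (0.0235), unfolded protein without saline replicate 2 (0.00628) and macrophages without saline replicate 3 (0.0207).

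The next comparison asked what remained 12 weeks after caerulein in WT cells. The gastric genes Pgc, Gkn3 and Muc6 were present in caerulein libraries and nearly absent with saline, while Tff2, also a gene of mucous neck cells, was high in both (2199 ± 608 and 2135 ± 193 CPM, n = 4 each, log2 0.04). Pgc (mm9 chromosome 17, 47863791 to 47871432, plus strand) stood at 31.2 ± 13.2 CPM (SD, n = 4) after caerulein and had no counts in the 4 saline libraries, against a floor of 0.0304 CPM. Gkn3 (mm9 chromosome 6, 87333262 to 87338929, minus strand) stood at 6.00 ± 4.27 CPM against no counts, at least 195-fold higher. Muc6, a gastric mucin gene (mm9 chromosome 7, 148819871 to 148841218, minus strand), stood at 4.23 ± 2.03 CPM against 1 count, a ratio with an interval of 75.6 to 16759. Each of the 4 caerulein libraries was above each saline library for Pgc and Gkn3. Their adjusted p-values by edgeR were 0.187 and 0.185 in the MD4 fit (Muc6, 0.108), and by DESeq2 7.72e-18 and 7.14e-12 (Muc6, 8.12e-08). The edgeR p for Pgc fell to 0.0334 when only the groups compared were fitted and to 0.0363 with sex as a covariate. Fam107b (mm9 chromosome 2, 3621285 to 3699414, plus strand) rose from 0.873 ± 0.202 to 10.5 ± 1.12 CPM (log2 3.58, SE 0.253, edgeR adjusted p = 6.67e-07).

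In the MD4 12-week comparison 6 genes passed by edgeR, 4 higher and 2 lower, while 582 had an unadjusted p under 0.05 and DESeq2 called 56. Under the naming rule the rises were Fam107b and Cyr61 (log2 1.07, SE 0.148, adjusted p = 0.00555). The other calls, below the level of the rule and chosen after their values were seen, were Pga5, a pepsinogen (log2 3.59, SE 0.515), Hopx (3.03, adjusted p = 0.0154), Iyd (-1.29, 0.00555) and Hmga1-rs1 (-3.75, 0.0335). Pga5 was lost without saline replicate 2 (0.0845). Hopx was lost when any of 4 libraries was left out, with adjusted p-values from 0.0553 to 0.0948, and Hmga1-rs1 when any of 6 was, from 0.0642 to 0.179. No member of the gastric list passed over all genes, and 5 of the 12 kept by the filter rose over the list alone. The list passed camera (median log2 0.97, adjusted p = 2.36e-15, 0.000491 with an estimated correlation). These members were Muc6, Gkn3, the water channel gene Aqp5 (log2 3.09), Ctse (3.05) and Agr2 (1.06). Lymphocyte markers moved with it, with no call over all genes and 2 of 5 when adjusted over the list alone (camera adjusted p = 1.87e-05, adjusted p = 0.0199 with an estimated correlation). They were the plasma cell genes Igj (log2 3.89) and Igkc (2.98), and the list summed to 2.86 ± 0.892 CPM against 0.937 ± 0.235. Ductal genes (22, of which 2 rose and 1 fell when adjusted over the list alone, adjusted p = 0.00444), interferon genes (22, adjusted p = 2.24e-07), wound genes (20, adjusted p = 4.04e-06) and islet markers (13, adjusted p = 5.25e-05) passed camera upward. None had a call over all genes, and each had an adjusted p = 0.279 with an estimated correlation. Cell cycle genes (24) passed it downward (adjusted p = 0.000150, adjusted p = 0.678 with an estimated correlation), but turned upward without saline replicate 4 (0.112). The 27 enzyme genes gave a camera adjusted p of 0.886 with 0 calls by edgeR, but passed downward without caerulein replicate 4 (0.00749). Cpa1 (-0.01), Ptf1a (0.06), Kras (-0.15), Krt19 (0.45), Sox9 (-0.39), Reg3b (-0.69) and Clu (-0.50) did not pass.

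**Figure D2:**
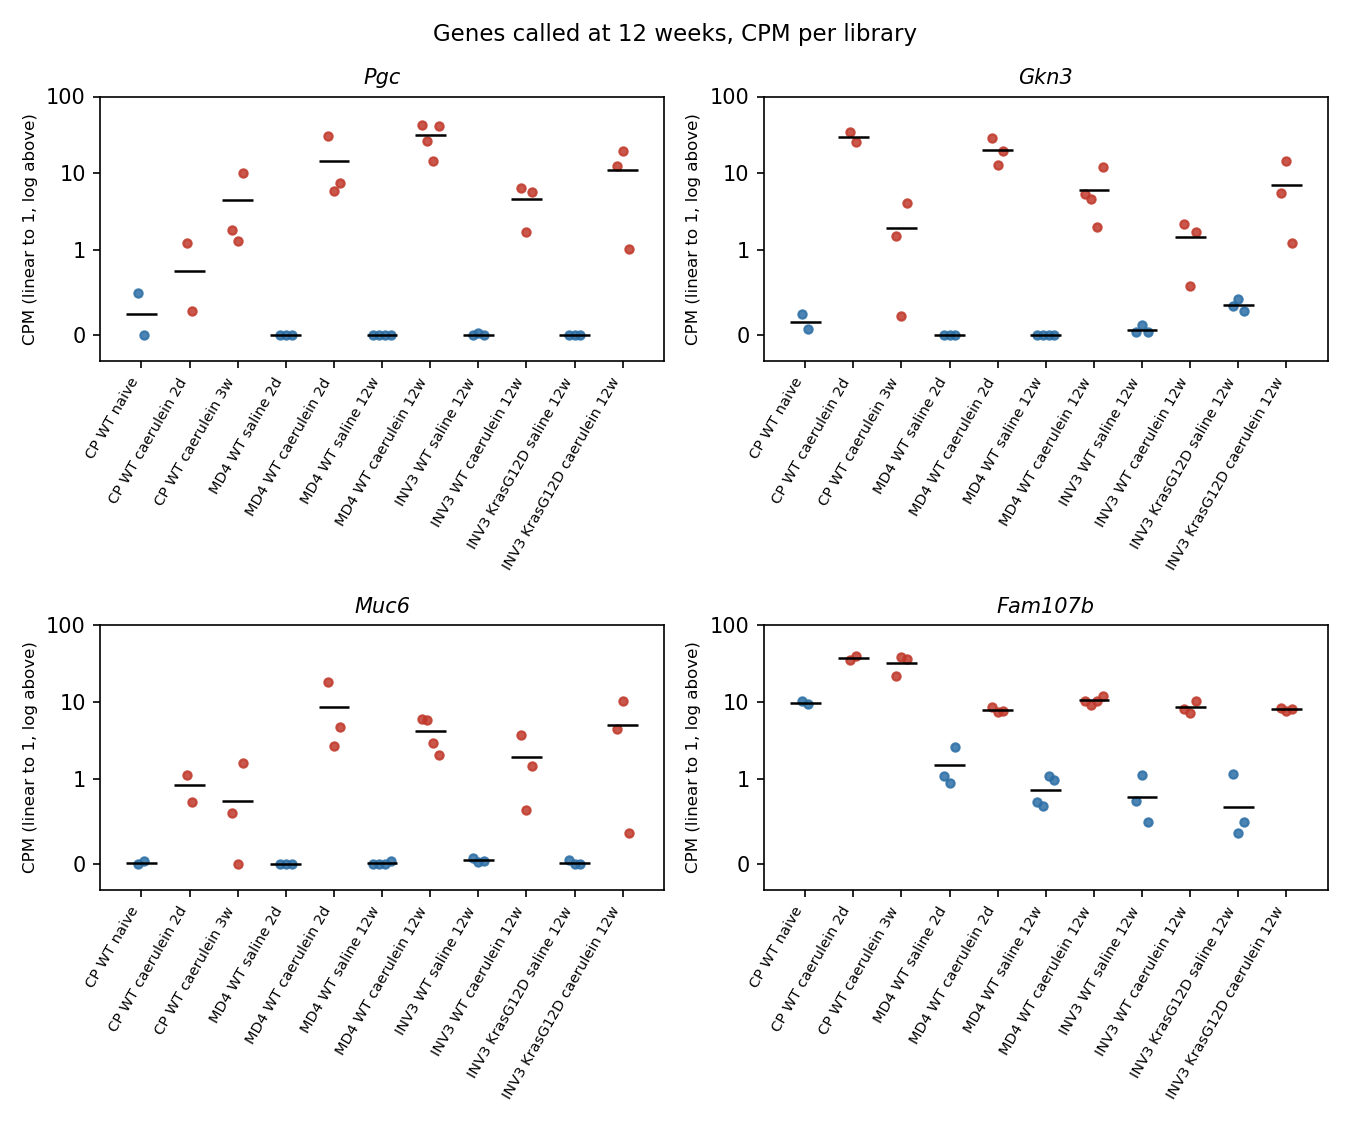
CPM of Pgc, Gkn3, Muc6 and Fam107b in each library of the 11 groups (points; red, caerulein; blue, saline or naive; bars, group means; the axis is linear to 1 and logarithmic above). At 12 weeks in MD4, Pgc averaged 31.2 CPM with caerulein and 0 with saline.

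When the WT 12-week libraries of MD4 and INV3 were joined (7 against 7, set as a covariate), 27 of 11254 genes passed edgeR, 18 higher and 9 lower. Pgc went from 1 count over the 7 saline libraries to 19.8 ± 17.1 CPM, a ratio with an interval of 609 to 134068 (adjusted p = 1.99e-06), and Lgals9, a galectin, from 9.35 ± 2.20 to 19.1 ± 4.61 CPM (log2 1.04, SE 0.158). Below the level of the rule and chosen after their values were seen were Fam107b (log2 3.50, SE 0.158, adjusted p = 1.25e-10), Muc6 (6.62, SE 0.634), Gkn3 (6.64, SE 0.751), Krt7 (1.45, SE 0.190) and Pdlim4 (2.00). Among the falls were Peli1 (-1.19), Cldn9 (-1.75) and Iyd (-1.10). With limma-voom, Gkn3 (0.0943) and Muc6 (0.0516) no longer passed. Of the 6 MD4 calls, Cyr61 (log2 0.67, adjusted p = 0.224), Hopx (2.06, 0.0924) and Hmga1-rs1 (-1.87, 0.806) did not pass in the joined fit, and in INV3 WT libraries alone Cyr61 stood at 0.14 and Hopx at 0.94 (adjusted p = 0.999 for both). Only 6 gastric genes passed the filter and entered the list test, and 2 rose (3 over the list alone, median log2 0.89). Camera gave an adjusted p of 1.31e-16, and 5.41e-05 with an estimated correlation. Of 4 lymphocyte markers 0 passed edgeR over all genes and 2 over the list alone, Igj (2.17) and Igkc (1.80). Their camera adjusted p was 4.47e-05, and 0.00915 with an estimated correlation.

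The 2-day genes were then tested as sets in later comparisons that shared no library with them. In MD4 at 12 weeks the 1397 up genes passed camera upward (median log2 0.07, 55.5% positive, adjusted p = 0.00267, adjusted p = 0.414 with an estimated correlation) and the 787 down genes downward (median -0.10, 30.9% positive, adjusted p = 5.96e-07, adjusted p = 0.283 with an estimated correlation). At 3 weeks in CP the medians were 0.69 and -0.36, with 77.0% and 23.3% positive (adjusted p = 1.70e-14 and 2.61e-08, adjusted p = 0.283 for each with an estimated correlation). In KrasG12D libraries the caerulein effect had medians of 0.25 and -0.08 (adjusted p = 6.64e-06 and 0.0215, and 0.356 and 0.463 with an estimated correlation). In WT INV3 libraries the adjusted p-values were 0.101 and 0.0139 (adjusted p = 0.579 and 0.463 with an estimated correlation). KrasG12D against WT with saline gave 0.0558 for the up set and 0.000732 for the down set (adjusted p = 0.568 and 0.388 with an estimated correlation), with medians of 0.03 and -0.10. With the 200 lowest-p genes per direction as the set, the up set at 12 weeks in MD4 gave 0.795. The MD4 up set was lost without saline replicate 1 (0.101) and the KrasG12D down set without mktC-1751 (0.224) or mktS-1731 (0.0508). The WT INV3 down set was lost without mtC-1777 (0.0904) and turned without mtS-1729 (0.509), and the genotype down set was lost without mtS-1729 (0.786). The up set passed without mtS-1662 in WT INV3 libraries (0.00352, and 0.00265 without mtC-1667) and between genotypes (0.00124, and 0.0191 without mtS-1663).

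The difference between the caerulein effects at 12 weeks and at 2 days was tested in the MD4 set. Secretory genes changed upward and cell cycle genes downward from the 2-day to the 12-week effect, the latter without passing camera as a list with an estimated correlation (adjusted p = 0.0751). Gal changed by 6.48 (log2, SE 0.591), Fxyd1 by 4.71 (SE 0.322), Pnlip by 4.48 (SE 0.390), Dusp26 by 4.46, Galnt6 by 4.25 and Cpa1 by 2.30 (SE 0.221, edgeR adjusted p = 2.74e-06). Ccna2 changed by -9.49 (SE 1.30), Mki67 by -8.50, Ube2c by -8.23, Cdc20 by -7.96 and Uhrf1 by -7.80. The edgeR test called 2173 genes, 1190 upward and 983 downward (80 and 10684 with total-count scaling). The enzymes changed in 25 of 27, 23 upward and 2 downward (24 and 2 when adjusted over the list alone, camera adjusted p = 1.35e-54, adjusted p = 0.0190 with an estimated correlation), with Cela2a at 2.95. All 24 cell cycle genes changed downward (camera adjusted p = 2.99e-33). Fibroblast markers went downward in 10 of 13 (camera adjusted p = 1.21e-06, adjusted p = 0.186 with an estimated correlation). Wound genes went downward in 6 of 20 (9 when adjusted over the list alone, camera adjusted p = 0.000646, adjusted p = 0.344 with an estimated correlation). Gastric genes changed upward in 1, Tff2 (2.81), and downward in 2 of 12 (camera adjusted p = 0.649), and their direction turned upward with total-count scaling. Ptf1a changed by 1.23 (SE 0.263, adjusted p = 0.00375), which turned to -0.38 with total-count scaling, and Clu by -0.85 (SE 0.224, 0.0142). Krt19 (0.06), Sox9 (-0.63), Reg3b (0.73) and Kras (-0.10) did not pass.

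Saline libraries at 12 weeks were compared with those at 2 days as the background of time. The clock gene Per1 fell from 19.2 ± 5.90 (n = 3) to 4.50 ± 0.867 CPM (n = 4; log2 -2.10, SE 0.278, edgeR adjusted p = 0.00850). The thiamine transporter gene Slc19a2 fell by 2.08 (SE 0.272), Arl5b fell by 1.45 (SE 0.214) and Cyr61 fell (mm9 chromosome 3, 145309935 to 145312949, minus strand) from 11.2 ± 1.10 to 4.88 ± 0.584 CPM (log2 -1.20, SE 0.157). In all 12 genes passed, 2 higher and 10 lower, and 1424 had an unadjusted p under 0.05. The count was 92 without saline 2-day replicate 3, 7 without 2-day replicate 1 and 5, 6 and 4 without saline 12-week replicates 1, 2 and 3. Arl5b was lost without 12-week replicate 3 (0.0589) or 2-day replicate 1 (0.0598). Lymphocyte markers fell in 1 of 5 (3 when adjusted over the list alone, camera adjusted p = 5.78e-08, adjusted p = 0.0197 with an estimated correlation), the call being Igj (-5.55), with a summed level of 10.1 ± 8.22 CPM at 2 days. Of the ERK list 0 of 16 passed edgeR over all genes and 5 when adjusted over the list alone (camera adjusted p = 5.78e-08, adjusted p = 0.0285 with an estimated correlation), among them Errfi1 (-1.89) and Dusp5 (-1.99). Immediate early genes fell in 1 of 17, Cyr61, and in 4 when adjusted over the list alone (camera adjusted p = 0.000315, adjusted p = 0.0290 with an estimated correlation). Reg genes (4 of 19 when adjusted over the list alone, adjusted p = 9.35e-09) and unfolded protein genes (7 of 22, adjusted p = 5.78e-08) passed camera downward, with an adjusted p = 0.0596 and 0.144 with an estimated correlation.

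In the CP set, 2 days of recovery were compared with naive libraries. Secretory genes were far lower, as Pnlip (log2 -7.43, SE 0.436, edgeR adjusted p = 1.41e-08), Cpa1 (-4.33, SE 0.344) and Gal (93.5 ± 17.6 to 0.211 CPM, log2 -8.76, SE 0.994), and genes of macrophages, fibroblasts and matrix were far higher. Thbs4, a matrix protein gene, reached 192 ± 17.9 CPM against 0.202 (log2 9.90, SE 0.768), and the complement gene C1qc rose by 5.89 (SE 0.279). Fibroblast markers summed to 6095 ± 295 CPM against 162 ± 175, macrophage markers to 3072 ± 65.4 against 103 ± 33.5, lymphocyte markers to 1249 against 110 and endothelial markers to 59.1 against 5.71. Islet markers summed to 766 against 2048 (n = 2 each). Changes within acinar cells were therefore not separated from a changed mix of cells in this comparison. The other largest changes were in Igkv1-110, Tnc, Nkd2 and Cpxm2, with 1 to 3 naive counts and ratio intervals of 290 to 63879, 243 to 3449, 116 to 25646 and 130 to 3875. The largest other falls were in Tmed11 (-6.41), Hamp2 (-6.20) and Rpl38-ps2 (-6.01). Tmed11 and Hamp2 were lost without library C2D_555 (0.0997 and 0.0735) or C2D_558 (0.104 and 0.0926), Tmed11 also without naive replicate 2 (0.0529), and Tnc with limma-voom (0.0545). By Xist and Y-linked genes both 2-day libraries were XY and the naive libraries 1 XX and 1 XY. Of 15832 genes 6501 passed edgeR, 3675 higher and 2826 lower. The count was 4251 without library C2D_558, and the split was 14352 higher and 125 lower with total-count scaling.

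Of the 27 enzymes 25 fell and Prss1 rose (3.03), also when adjusted over the list alone (camera adjusted p = 9.79e-32), and Pla2g1b fell by 5.96. Acinar factors fell in 8 of 12 (camera adjusted p = 0.000414), with Spdef at -1.76, Bhlha15 at -1.90 and Ptf1a at -0.93 (SE 0.266, adjusted p = 0.0119), which turned to 0.73, 0.59 and 1.58 with total-count scaling. Ptf1a was lost without naive replicate 1 (0.0527), library C2D_555 (0.0760) or C2D_558 (0.0575). Oxidative phosphorylation genes fell in 17 of 20 (18 when adjusted over the list alone, camera adjusted p = 3.52e-06), such as Ndufa1 (-1.82, but 0.66 with total-count scaling). Macrophage markers rose in 16 of 18 (camera adjusted p = 1.13e-31, Cd68 5.27) and fibroblast markers in 14 of 16 (16 when adjusted over the list alone, camera adjusted p = 2.32e-11, Pdgfrb 4.58). Wound genes rose in 21 of 25 with 1 fall (camera adjusted p = 9.43e-12, Lgals3 5.69, Mmp7 5.23) and cell cycle genes in 24 of 24 (camera adjusted p = 7.28e-08, Top2a 4.17). ERK targets rose in 14 of 20 with 1 fall (camera adjusted p = 8.10e-07, Dusp4 5.74, Phlda1 4.11). Reg and NF-kB genes rose in 18 of 26 with 3 falls (19 and 3 when adjusted over the list alone, camera adjusted p = 3.50e-06, Tnfaip2 4.79, Cd14 3.97). Interferon genes rose in 19 of 25 with 1 fall (20 and 1 when adjusted over the list alone, camera adjusted p = 3.45e-05, Nlrc5 3.99) and endothelial markers in 7 of 12 (8, camera adjusted p = 6.12e-05, Eng 5.46). Progenitor factors rose in 14 of 23 with 2 falls (15 and 2 when adjusted over the list alone, camera adjusted p = 0.000342, Runx1 3.98). Lymphocyte markers rose in 9 of 14 (11 when adjusted over the list alone, camera adjusted p = 0.00119) and gastric genes in 8 of 15 with 2 falls (9 and 2, camera adjusted p = 0.0212, Dclk1 3.99, Tff2 -5.48). None of these lists passed with an estimated correlation, where adjusted p ranged from 0.101 for the enzymes and macrophages to 0.328 for oxidative phosphorylation and endothelium. The gastric list was lost when any 1 of the 4 libraries was left out (0.0753 to 0.167). Islet markers fell in 2 of 14 (camera adjusted p = 0.00776, but 0.377 without naive replicate 2, adjusted p = 0.473 with an estimated correlation). The ductal (0.961), AP-1 (0.195), immediate early (0.0525), unfolded protein (0.133), cholesterol (0.427), erythroid (0.133, with 3 of 4 higher), adipocyte (0.961) and sex-linked (0.961) lists did not pass camera. Fosl1 rose from 0.232 ± 0.152 to 2.51 ± 0.174 CPM (log2 3.40, adjusted p = 0.000233). Kras (0.32), Krt19 (0.46), Sox9 (-0.36, 2.12 with total-count scaling), Clu (-0.90), Reg3b (-2.35) and Onecut2 (1.45) did not pass.

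At 3 weeks in the CP set, against the same 2 naive libraries, markers of fibroblasts, endothelium and macrophages were high and the enzyme share of counts was 70.8% against 73.9%. Cpa1 was at -0.64 (adjusted p = 0.136), and none of 27 enzymes passed edgeR over all genes (unadjusted p under 0.05 in 4282 genes of all tested, camera adjusted p = 0.0238, adjusted p = 0.695 with an estimated correlation). The enzyme list was lost without 3-week replicate 4 (0.0947) or naive replicate 1 (0.0549). Mgp, a matrix protein gene, rose from 1.43 ± 1.39 (n = 2) to 234 ± 83.7 CPM (n = 3; log2 7.36, SE 0.935, edgeR adjusted p = 0.00474). Kcne4 rose by 7.29 (SE 0.511), Igfbp3 by 7.29 (SE 0.822) and the endothelial gene Pecam1 by 6.99 (SE 1.01), and Cpxm2 had a ratio interval of 87.4 to 2617. The largest falls were Scn4b (-1.73), Prom2 (-1.47), Ankrd24 (-1.44), Nphs1 (-1.43) and Dagla (-1.39). Igfbp3 was lost without naive replicate 1 (0.0545) or 2 (0.0795) and Pecam1 without naive replicate 2 (0.0760). In all 2463 genes passed, 2024 higher and 439 lower (2553 and 48 with total-count scaling). Fibroblast markers rose in 13 of 16 (16 when adjusted over the list alone, camera adjusted p = 9.44e-22) and summed to 3582 ± 140 CPM. Macrophage markers rose in 16 of 18 (camera adjusted p = 3.20e-30) and summed to 975 ± 67.2 CPM, and endothelial markers in 11 of 12 (12 when adjusted over the list alone, camera adjusted p = 1.60e-15) with a sum of 140 CPM. With them rose wound genes, 17 of 25 with 1 fall (18 rises when adjusted over the list alone, camera adjusted p = 7.82e-15, Mmp14 2.43), and Reg and NF-kB genes, 16 of 26 (camera adjusted p = 9.23e-12, Tnfaip2 4.92). Interferon genes rose in 18 of 25 (20 when adjusted over the list alone, camera adjusted p = 5.52e-11, Gbp2 3.95). ERK targets rose in 9 of 20 with 2 falls (12 and 2 when adjusted over the list alone, camera adjusted p = 0.000101, Phlda1 3.01). Acinar factors fell in 6 of 12 (9 when adjusted over the list alone, camera adjusted p = 0.000258). Among them were Nr5a2 (-0.97, SE 0.201) and Ptf1a (13.9 ± 2.41 to 7.64 ± 2.15 CPM, log2 -0.86, SE 0.244, adjusted p = 0.0255), the latter lost without naive replicate 1 (0.101) or 3-week replicate 3 (0.0840). With an estimated correlation adjusted p was 0.144 for macrophages, 0.184 for ERK targets and 0.160 for the other lists just named. Progenitor factors (8 of 23, adjusted p = 0.00596, Runx1 3.10, Id3 5.51) and gastric genes (4 of 15, adjusted p = 0.0117, Dclk1 3.19) also passed camera, with adjusted p = 0.248 for both with an estimated correlation. Fosl1 rose by 3.15 on the log2 scale (SE 0.554, adjusted p = 0.000866), and Kras (0.10), Krt19 (0.19), Sox9 (-0.75), Clu (-0.84), Reg3b (-0.52) and Onecut2 (-0.78) did not pass.

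In the INV3 set, counts per gene do not separate the mutant from the normal Kras allele, and Kras levels did not mark the genotype. Kras stood at 4.15 ± 0.719 CPM in WT saline, 4.13 ± 0.406 in WT caerulein, 4.91 ± 0.475 in KrasG12D saline and 3.72 ± 0.117 in KrasG12D caerulein libraries (SD, n = 3 each). The first INV3 comparison asked what caerulein left in WT cells at 12 weeks. Fam107b rose from 0.790 ± 0.317 to 8.54 ± 1.66 CPM (log2 3.40, SE 0.311, edgeR adjusted p = 0.000324) and Pdlim4, a gene of the actin cytoskeleton (mm9 chromosome 11, 53868430 to 53882516, minus strand), by 2.15 (SE 0.333, 0.0481), both below the level of the rule and chosen after their values were seen. They were the only calls by edgeR among 11382 genes (433 at an unadjusted p under 0.05; 18 by DESeq2), and Pdlim4 was lost when any of 5 libraries was left out (mtS-1662, mtS-1663, mtC-1726, mtS-1729 or mtC-1777). The count was 5 without mtC-1667, 4 without mtS-1729 and 1 without mtS-1663, mtC-1726 or mtC-1777, and 132 with no filter on low counts. Pgc stood at 4.64 ± 2.56 CPM against 1 count over the saline libraries, Gkn3 at 1.49 ± 0.830 against 0.0652 and Muc6 at 1.93 ± 1.59 against 0.0466, the last pair with adjusted p = 0.999 over all genes and 0.0521 when adjusted over the list alone. The gastric list (8 genes, adjusted p = 0.00132) passed camera upward. The cell cycle (23, adjusted p = 5.84e-05), ERK (15, adjusted p = 9.41e-05), macrophage (14, adjusted p = 3.92e-08) and fibroblast (11, adjusted p = 3.81e-06) lists passed it downward. These lists had 0 edgeR calls over all genes and, when adjusted over the list alone, 2 in the ERK list. With an estimated correlation adjusted p was 0.534 for the cell cycle and 0.469 for the others. The cell cycle and ERK lists were lost without saline library mtS-1662 (0.876 and 0.0830), the fibroblast list without mtS-1663 (0.457) or mtC-1667 (0.0591).

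Caerulein was then compared with saline at 12 weeks in KrasG12D cells. Fam107b again rose, from 0.668 ± 0.415 to 8.07 ± 0.369 CPM (log2 3.52, SE 0.311, edgeR adjusted p = 0.000215), and B4galt4, a galactosyltransferase (mm9 chromosome 16, 38742377 to 38769162, plus strand), fell from 24.7 ± 3.34 to 11.2 ± 1.36 CPM (log2 -1.14, SE 0.131, 0.00124). The other rises under the rule were Fam13a (log2 1.32, SE 0.181), Fnip2 (1.31), the fatty acid desaturase gene Fads2 (1.05), Ypel2 (1.05), Zfp395 (1.03), the laminin gene Lama5 (0.81), Ogt (0.75), Lgr4 (0.71) and Zfp740 (0.57). The other falls were Try10 (-1.30), a trypsinogen with near-identical copies, the selenoprotein genes Sepw1 (-0.79) and Selm (-0.73), Ppa1 (-0.78), Nudt4 (-0.76), the respiratory chain gene Cox6c (-0.75), Tfdp2 (-0.66), Tmem64 (-0.65) and Cd320 (-0.62). In all 61 genes passed, 42 higher and 19 lower, and 2161 had an unadjusted p under 0.05. Without saline library mktS-1732 only 2 genes passed, Fam107b and B4galt4 among the named genes. The count was 340 without saline library mktS-1669, 20 without saline mktS-1731 and 8, 4 and 85 without caerulein libraries mktC-1737, mktC-1751 and mktC-1780. The 3 caerulein libraries were XX by Xist and Y-linked genes while the saline libraries were 1 XX and 2 XY, and 8 genes passed with sex as a covariate. Both the count and the balance of directions depended on the setting. With the number series as a covariate 269 genes were higher and 343 lower (612), with only the groups compared 124 and 132 (256), by DESeq2 183 and 191 (374) and with no filter on low counts 456 and 370 (826). With a filter at 5 CPM they were 28 and 8 (36) and with total-count scaling 64 and 7.

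Gastric genes gave high but variable values in these libraries. Pgc stood at 11.02 ± 9.36 CPM against no counts (adjusted p = 0.0947 by edgeR, 0.0122 without caerulein library mktC-1780, 2.92e-07 by DESeq2). Gkn3 stood at 7.12 ± 6.81 against 0.354 (0.0712 by edgeR) and Muc6 at 5.09 ± 5.08 against 2 counts, a ratio interval of 71.5 to 2147 (0.0743 by edgeR). Of 8 gastric genes 3 rose when adjusted over the list alone and 0 over all genes by edgeR (camera adjusted p = 0.0296, adjusted p = 0.673 with an estimated correlation), and the list was lost without caerulein library mktC-1737 (0.119). Oxidative phosphorylation genes fell in 1 of 20, and in 12 when adjusted over the list alone (camera adjusted p = 4.43e-08), such as Cox7a2 (-0.58) and Atp5o (-0.52). Enzymes fell in 2 of 27 when adjusted over the list alone (camera adjusted p = 5.26e-05, Ctrc -1.07, Zg16 -0.63), and unfolded protein genes in 4 of 22 (camera adjusted p = 0.000453, Chac1 -1.83, Sesn2 -0.89), a list lost without saline library mktS-1669 (0.0531). Progenitor factors rose in 4 of 17 when adjusted over the list alone (camera adjusted p = 0.00194, Ets1 1.17, Stat3 0.52) and ductal genes in 1 of 21, Tspan8 (3.17, camera adjusted p = 0.00187). Fibroblast markers summed to 22.9 ± 5.25 CPM against 12.9 ± 7.36 and passed camera upward (adjusted p = 0.0464, but 0.189 without saline library mktS-1669). Macrophage markers summed to 15.1 ± 7.45 CPM against 33.1 ± 16.6 and passed it downward (adjusted p = 0.00237, but 0.0779 without saline library mktS-1731). With an estimated correlation adjusted p lay between 0.673 and 0.747 for every list in this paragraph. Kras (-0.40, adjusted p = 0.181), Ptf1a (-0.25), Cpa1 (-0.12), Krt19 (0.35), Sox9 (0.49), Clu (-0.73) and Reg3b (1.39, 0.103) did not pass.

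Without pancreatitis, 3 genes differed between KrasG12D and WT cells by edgeR. B4galt4 was higher in KrasG12D (24.7 ± 3.34 against 13.8 ± 0.196 CPM, log2 0.84, SE 0.131, adjusted p = 0.0357), and the bile acid receptor gene Nr1h4 (-1.96) and Dclk3 (-2.11), chosen after their values were seen, were lower. At an unadjusted p under 0.05 there were 708 genes, and DESeq2 called 30. The count was 0 without mktS-1732 or mtS-1662, 1 without mktS-1731 or mtS-1663 and 23 without mktS-1669, and each of the 3 genes was lost without at least 4 of the 6 libraries. By Xist and Y-linked genes the WT libraries were 2 XX and 1 XY and the KrasG12D libraries 1 XX and 2 XY. Calls were 1 with sex as a covariate, 10 with the number series, 206 with no filter on low counts and 0 with limma-voom, a filter at 5 CPM, total-count scaling or only the groups compared. Kras was at 0.24 (SE 0.153, adjusted p = 0.883). ERK targets did not pass camera (adjusted p = 0.0640), with 0 of 15 called by edgeR and Dusp4 at 2.45 (adjusted p = 0.601). The list passed without mtS-1662 (0.000361), mtS-1663 (0.00903) or mktS-1732 (0.0118) and stood at 0.995 without mtS-1729. Interferon genes did not pass it either (adjusted p = 0.0599), with 0 of 15 over all genes and 2 when adjusted over the list alone, B2m (0.89) and Stat1 (0.56). They passed without mtS-1663 (0.00227) or mktS-1732 (0.0218) and stood at 0.387 without mtS-1729. Macrophage markers were higher and fibroblast markers lower (camera adjusted p = 0.0251 for both, adjusted p = 0.838 with an estimated correlation). The macrophage list was lost without mktS-1731 (0.415), mktS-1732 (0.377), mtS-1662 (0.254) or mtS-1729 (0.0996). The fibroblast list was lost without mktS-1669 (0.238), and its direction turned without mtS-1663 (0.667).

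After caerulein, 6 of 15 targets of ERK, a kinase downstream of Kras, were higher in KrasG12D than in WT libraries by edgeR when adjusted over the list alone, and none over all genes. Dusp4, a phosphatase induced by ERK (mm9 chromosome 8, 35870351 to 35882948, plus strand), stood at 0.769 ± 0.249 CPM in KrasG12D and 0.0683 ± 0.0355 in WT libraries (log2 3.37, SE 0.739). The feedback inhibitors Spred2 and Spred1 stood at 4.28 ± 0.370 against 1.73 ± 0.508 (1.31, SE 0.307) and 5.62 ± 0.444 against 2.62 ± 0.960 (1.11, SE 0.283). Over all genes their edgeR adjusted p-values were 0.144, 0.220 and 0.260. Over the list alone they were 0.00492 for Dusp4, 0.00578 for Spred2 and 0.00607 for Spred1 and Dusp5, and Spry1 and Etv5 also passed. The list passed camera (median log2 0.87, adjusted p = 1.53e-14, adjusted p = 0.0505 with an estimated correlation). With saline, Spred2 stood at 2.57 ± 0.940 CPM in KrasG12D and 3.01 ± 1.21 in WT libraries, and Spred1 at 4.51 ± 0.861 and 4.95 ± 1.87 CPM. Dusp4 and Etv5 were higher in KrasG12D with saline already, at 0.466 ± 0.394 against 0.0780 ± 0.0432 and 8.64 ± 3.27 against 3.99 ± 2.57 CPM, without passing (log2 2.45 and 1.11, edgeR adjusted p = 0.601 and 0.802). The interaction was 1.53 for Spred2 (SE 0.432, adjusted p = 0.863), 1.25 for Spred1, 0.93 for Dusp4, 0.95 for Etv5 and 0.70 for Dusp5. Over the list alone their adjusted p-values were 0.0490, 0.0536, 0.596, 0.562 and 0.369, in that order. The list gave a camera adjusted p of 0.000137 in the interaction (0.704 with an estimated correlation).

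**Figure D3:**
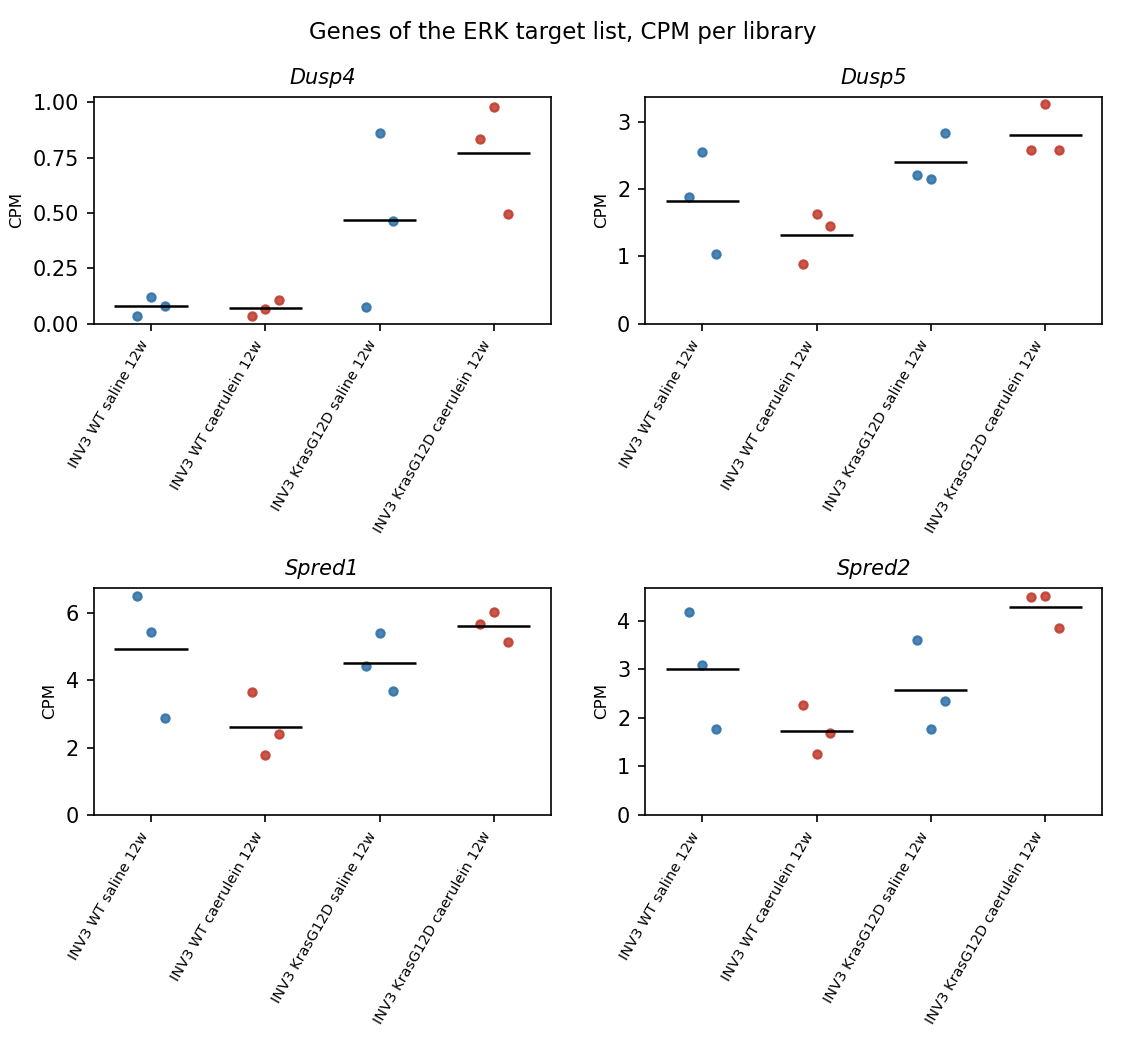
CPM of Dusp4, Dusp5, Spred1 and Spred2 in each INV3 library (points; red, caerulein; blue, saline; bars, group means). After caerulein, Dusp4 averaged 0.769 CPM in KrasG12D and 0.0683 in WT libraries.

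Over all genes 9 passed edgeR between the genotypes after caerulein (830 at an unadjusted p under 0.05; 57 by DESeq2). Under the rule these were Bex2 (log2 1.58, SE 0.214), the metal transporter gene Slc39a8 (1.12, SE 0.165), Slc25a35 (1.05, SE 0.138) and Sepw1 (-0.85, SE 0.147), with adjusted p-values from 0.00604 to 0.0446. The count was 0 without mktC-1737 or mtC-1777, 1 without mktC-1751, 2 without mtC-1667 and 26 without mktC-1780. It was 1 with total-count scaling, 4 with a filter at 5 CPM, 31 with the number series as a covariate, 34 with only the groups compared and 297 with no filter on low counts. Ductal genes (2 of 21 when adjusted over the list alone, Cftr 1.16 and Epcam 0.51, camera adjusted p = 0.000176), wound genes (18, adjusted p = 0.000332) and gastric genes (3 of 8 when adjusted over the list alone, adjusted p = 0.0210, Gkn3 2.26) passed camera upward, with fibroblast markers (11, adjusted p = 1.80e-05). Oxidative phosphorylation genes (20, adjusted p = 1.49e-05) and islet markers (12, adjusted p = 0.00126) passed it downward. All of these lists had 0 edgeR calls over all genes and an adjusted p = 0.449 with an estimated correlation. The gastric list was lost without KrasG12D library mktC-1737 (0.142) or mktC-1751 (0.144) and the islet list without WT library mtC-1726 (0.243). The interaction of genotype and caerulein gave 0 calls by edgeR over all genes, with 638 at an unadjusted p under 0.05, 5 calls by DESeq2 and 0 by limma-voom. With no filter on low counts edgeR called 136 genes. Over all genes that passed the filter, the caerulein effects of the genotypes were thus not shown by edgeR to differ, and Kras gave -0.39 (adjusted p = 0.863). Fibroblast markers passed camera in the interaction (adjusted p = 1.64e-07, adjusted p = 0.704 with an estimated correlation).

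Log2 fold changes were correlated across genes between comparisons with no library in common, for 11 pairs with 2 gene filters each. Genes are not independent replicates. The MD4 and CP 2-day effects had a Pearson r of 0.665 and a Spearman rho of 0.647 over 12559 genes, with 1159 shared higher genes against 423 for independent lists and 1473 shared lower genes against 481. The MD4 2-day and CP 3-week effects had r = 0.433 and rho = 0.334, with 518 shared higher genes against 195 (hypergeometric adjusted p = 1.22e-122) and 178 lower against 75.8 (2.55e-31). At 12 weeks the caerulein effects in MD4 and INV3 WT cells had r = 0.393 and rho = 0.154 and 1 shared call, Fam107b. The effects in INV3 WT and KrasG12D cells had r = 0.377 and rho = 0.300 and 2 shared calls, Fam107b and Pdlim4 (5.85e-05). Fam107b also rose at the earlier times, to 7.84 ± 0.660 from 1.54 ± 0.903 CPM in MD4 at 2 days (log2 2.35, adjusted p = 3.93e-06 by edgeR). In CP it stood at 37.0 CPM at 2 days (log2 1.91, adjusted p = 4.69e-05) and 32.4 ± 9.35 at 3 weeks (1.72, adjusted p = 0.000174) against 9.86 in naive libraries.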

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

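Total-count scaling and the comparison with other splits of the samples were chosen after the results of this part were seen.

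Groups of 4 libraries were searched for a library whose gap to its nearest neighbour took more of the group's range than Dixon's 95% critical value allows. Chance flags about 1 in 20 groups, so 5.6 were due by chance among 112 groups of values, and 16 were found. In 3 of these the other libraries had no counts, so any count gives a ratio of 1, and without such groups 13 of 107 were found against 5.35 due by chance. In MD4 saline libraries at 12 weeks, replicate 4 stood apart in cell division genes, with gap ratios of 0.9315 for Ccna2 (1.64 CPM against 0.088 to 0.194 in the others), 0.8821 for Cdc20, 0.9002 for Mki67 (1.93 against 0.097 to 0.28), 0.8946 for Ube2c and 0.8319 for Uhrf1. The same library stood apart in summed markers of fibroblasts (0.8422; 9.79 CPM against 4.76 to 5.55) and of erythroid cells (0.8589; 6.42 against 0.484 to 1.32), and in Reg3b (0.8293; 4384 CPM against 329 to 1021). The 3 that decide nothing were Aqp5 (2 counts, 0.065 CPM) and Ctse and Muc6 (1 count each, 0.033 CPM), with a gap ratio of 1. In the same group replicate 3 stood apart for Slc28a3 (0.936; 1.28 CPM against 0.949 to 0.97). In MD4 caerulein libraries at 12 weeks, replicate 2 stood apart for Cdc20 (0.874; 0.658 CPM against 0.039 to 0.117) and Uhrf1 (0.8758; 0.439 against 0.117 to 0.157), replicate 1 for Ptger4 (0.875; 3.70 against 2.66 to 2.79) and replicate 4 for Tff2 (0.9244; 3109 against 1839 to 1935). The last library also stood apart over the whole profile, with Spearman correlations of 0.928, 0.930 and 0.928 to the other 3, which had 0.980 to 0.982 among themselves, and with a TMM factor of 0.612 against 0.751 to 0.890. Without it the MD4 12-week comparison gave 7 calls by edgeR, Hmga1-rs1 being lost (adjusted p = 0.0642), and the enzyme list passed camera downward (0.00749). No explanation of these libraries was tested. Without saline replicate 4 the MD4 12-week comparison gave 11 calls by edgeR in place of 6, and the cell cycle list turned upward (camera adjusted p = 0.112).

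The caerulein effect at 12 weeks differed from that at 2 days in the MD4 set, by the test of the difference itself (edgeR). It called 2173 genes. The log2 differences of named genes were 6.48 for Gal, 4.71 for Fxyd1, 4.48 for Pnlip, 4.46 for Dusp26, 4.25 for Galnt6, 2.95 for Cela2a, 2.81 for Tff2, 2.30 for Cpa1 and 1.23 for Ptf1a, the last -0.38 with total-count scaling. They were -9.49 for Ccna2, -8.50 for Mki67, -8.23 for Ube2c, -7.96 for Cdc20, -7.80 for Uhrf1 and -0.85 for Clu. Among 100 splits of the 14 libraries, the real one included, 15 gave as many calls, the highest other value being 3349. All 15 kept or fully exchanged the caerulein and saline labels at 2 days, and so the 2-day effect itself, so this count does not show whether chance can be excluded.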

How the results depend on the processing

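Total-count scaling, sex as a covariate and the splits of the samples were chosen after the data were seen. Over the settings run, 137 of 209 counts of calls stayed within 1.5 times the value reported and 72 did not. Of 4894 fold changes of named genes, 4398 kept their side of the threshold (uncalled turns included), 344 were lost, 141 gained and 11 turned. Of 1806 tests of lists and 2-day sets, 1558 kept theirs, 175 were lost, 65 gained and 8 turned. Of 16 overlap values 9 held. Counts of calls were within 1.5 times in all 12 comparisons with RLE size factors and without the enzyme list, which kept 304 of 305 and 285 of 286 named genes. The list tests rested on the preset correlation, since 78 of 112 were lost with an estimated one. With fry, which asks whether a list changed at all and not whether it changed more than other genes, 34 of 102 were lost. When 1 library was left out, counts moved by more than 1.5 times in 5 of 6 fits for each INV3 comparison of 3 with 3 libraries and in 5 of 7 between MD4 saline times, but in 1 of 8 at 12 weeks in MD4 and 1 of 4 at 2 days in CP. Depth limited the low genes, as a floor of 0.0304 CPM for Pgc in MD4 saline libraries at 12 weeks shows. For the values that follow the cause was not tested, except where fewer libraries or genes were fitted by construction.

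With no filter on low counts, calls by edgeR were 19 in the MD4 12-week comparison, 66 between MD4 saline times, 132 for caerulein in INV3 WT, 826 for caerulein in KrasG12D, 206 and 297 for genotype with saline and after caerulein, and 136 in the INV3 interaction. With a filter at 5 CPM they were 1 for INV3 WT caerulein, 36 for KrasG12D caerulein, 0 and 4 for genotype with saline and after caerulein, and 6 in the joined WT sets. DESeq2 called 56 genes in the MD4 12-week comparison, 131 between saline times, 18 for INV3 WT caerulein, 374 for KrasG12D caerulein, 30 and 57 for genotype with saline and after caerulein, 5 in the INV3 interaction and 65 in the joined sets. With limma-voom the counts were 3 in the MD4 12-week comparison, 5 between saline times, 1 for INV3 WT caerulein and 0 for genotype with saline. Fitting only the groups compared gave 13, 38, 1, 256, 0 and 34 calls for MD4 12 weeks, saline times, INV3 WT caerulein, KrasG12D caerulein and genotype with saline and after caerulein. With the number series of INV3 titles as a covariate, KrasG12D caerulein gave 612 calls and genotype 10 with saline and 31 after caerulein. With sex as a covariate there were 67 calls between saline times, 5 for INV3 WT caerulein, 8 for KrasG12D caerulein and 1 for genotype with saline.

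Whether MD4 replicate numbers mark pairs stays open on so few values. Deviations from group means of caerulein and saline libraries of the same number correlated by -0.03, -0.12 and -0.16 at 2 days. At 12 weeks r was 0.05, -0.03, 0.16 and 0.08. Not every library correlated best with its own number. With the replicate block, calls between saline times were 4, and the other MD4 counts were 4147 at 2 days, 9 at 12 weeks and 1834 for the difference of effects.

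With total-count scaling, calls were 11673 at 2 days in MD4, 3 at 12 weeks, 10764 for the difference of effects, 14477 at 2 days in CP, 1 for INV3 WT caerulein, and 0 and 1 for genotype with saline and after caerulein. Log2 changes turned at 2 days in MD4 for Kras (1.56), Ptf1a (0.42), Xbp1 (0.53), Muc1 (0.27) and Ndufa1 (0.32), in the difference of effects for Ptf1a (-0.38), and at 2 days in CP for Ptf1a (1.58), Sox9 (2.12), Spdef (0.73), Bhlha15 (0.59) and Ndufa1 (0.66). Camera turned downward at 2 days in MD4 for Reg genes (adjusted p = 0.00279) and macrophages (0.0122) and upward for oxidative phosphorylation (0.0732). It turned for gastric genes upward in the difference of effects (0.000407) and downward at 2 days in CP (0.778). The cause of these turns was not tested.

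Leaving out 1 library at a time gave 4 to 11 calls at 12 weeks in MD4 (11 without saline replicate 4), 4 to 92 between saline times (4 without 12-week replicate 3, 92 without 2-day replicate 3), 4251 to 6268 at 2 days in CP (4251 without C2D_558) and 1 to 5 for INV3 WT caerulein (5 without mtC-1667). KrasG12D caerulein gave 2 to 340 (without mktS-1732 and mktS-1669), genotype with saline 0 to 23 (the same libraries) and genotype after caerulein 0 to 26 (without mktC-1737 and mktC-1780). The cell cycle list at 12 weeks in MD4 ranged from 8.90e-11 to 0.112, turning without saline replicate 4, and the fibroblast list for genotype with saline from 8.85e-07 to 0.667, turning without mtS-1663. Camera adjusted p for the 2-day up set ranged from 1.58e-07 to 0.101 at 12 weeks in MD4, from 0.00265 to 0.903 for INV3 WT caerulein and from 0.00124 to 0.786 for genotype with saline. For the down set it ranged from 0.00133 to 0.224 for KrasG12D caerulein, from 3.53e-06 to 0.786 for genotype with saline and from 0.000281 to 0.509 for INV3 WT caerulein, the last turning without mtS-1729.

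Other settings of the 2-day sets changed these camera results. With an estimated correlation the adjusted p was 0.414 (up) and 0.283 (down) at 12 weeks in MD4, 0.283 for both at 3 weeks in CP, 0.463 (down) for INV3 WT caerulein, 0.356 (up) and 0.463 (down) for KrasG12D caerulein and 0.388 (down) for genotype with saline. With sets taken from CP at 2 days the down set gave 0.0639 in MD4, 0.0711 for INV3 WT caerulein and 0.476 for genotype with saline. The 200 lowest-p genes gave 0.795 for the up set in MD4. For genotype with saline the up set passed with the 200 genes (0.0478), no fold threshold (0.0479, the down set then 0.260), no markers of other cells (0.0418), RLE size factors (0.0453), a 5 CPM filter (5.12e-05), sex as a covariate (0.000901), only the groups compared (0.0382) and the number series (0.0326). For INV3 WT caerulein it passed with the 5 CPM filter (0.000133) and only the groups compared (0.0136), and the KrasG12D down set was lost with sex as a covariate (0.419).

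Across genes at 10 CPM or more, Spearman's rho of the MD4 and CP 2-day effects was 0.692. Between MD4 at 2 days and KrasG12D caerulein r was 0.131, and the overlaps were lost upward (adjusted p = 1.00, fewer genes being tested) and downward (0.0897). For the 12-week effects r was 0.315 between MD4 and INV3 WT, and r was 0.458 and rho 0.477 between INV3 WT and KrasG12D.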

Other observations

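The other splits of the samples, both tests of the gastric genes, the sex covariate, the comparison of covariates, the lists in the saline split and the following of the 27 calls into other comparisons were chosen after the results were seen, as were the genes named here outside the naming rule.

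The 27 genes called in the joined WT 12-week fit, 18 higher and 9 lower, were followed in comparisons that share no library with it. At 2 days in MD4, 17 of the 18 higher genes had the same sign and 16 were called, and all 9 lower genes had the same sign and 8 were called (52.4% and 47.6% of all genes had these signs). At 3 weeks in CP the numbers were 16 and 8 of the 18, and 6 and 3 of the 9. In KrasG12D libraries all 18 had the same sign and 5 were called, and of the lower genes 8 of 9 had the same sign and 1 was called. Krt7, a keratin of duct cells, changed by 2.61 on the log2 scale at 2 days (adjusted p = 1.16e-06), by 0.83 at 3 weeks (adjusted p = 0.00535) and by 1.26 in KrasG12D libraries (adjusted p = 0.119), all by edgeR. Mfge8, a secreted glycoprotein, rose by 2.86, 1.67 and 1.58 in the same comparisons, and Iyd, an iodotyrosine deiodinase, fell by 2.97 and 1.80 and stood at -1.31 in KrasG12D libraries (adjusted p = 0.101).

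Genes called for caerulein in KrasG12D cells at 12 weeks overlapped with those called at 2 days in MD4. Of 40 higher genes measured in both, 14 were shared against 6.04 for independent lists (hypergeometric adjusted p = 0.00464), among them Fam107b, Mecom, Mfge8, Timp2, Slit3 and Cldn2. Of 18 lower genes 9 were shared against 3.50 (hypergeometric adjusted p = 0.00956), among them B4galt4, Try10, Sepw1, Selm, Cox6c and Cldn9. Neither overlap passed among genes at 10 CPM or more (1.00 and 0.0897), and the number of KrasG12D calls depends on single libraries. Without mktS-1732 2 calls were left, while the median log2 change of the 61 genes was 0.868 against 0.929 with all libraries.

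Numbers of edgeR calls were set against other splits of the same libraries, the real split included. In 1 of 35 splits at 12 weeks in MD4 (6 calls, highest other 1), 1 of 35 between MD4 saline times (12, highest other 1) and 1 of 100 in the joined WT sets (27, highest other 1) there were as many calls. These shares are under 0.05 but unadjusted. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. There, as many calls came from 1 split at 2 days in MD4 (4414, highest other 3), 2 for INV3 WT caerulein (2, highest other 3), 1 for KrasG12D caerulein (61, highest other 0), 2 for genotype with saline (3, highest other 1372) and 1 for genotype after caerulein (9, highest other 2). The INV3 interaction had 0 calls, which all 100 splits reach whatever the data, so this count does not bear on chance (highest other 491).

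Some gastric-type genes were higher in WT acinar cells 12 weeks after caerulein, though Tff2 was not (2199 ± 608 against 2135 ± 193 CPM in MD4). Pgc, Gkn3, Muc6, Pga5 and Gif summed to 44.3 ± 18.2 CPM (SD, n = 4) against 0.200 ± 0.152 in MD4 and to 10.3 ± 5.88 (n = 3) against 0.659 ± 0.106 in INV3. Stomach or duodenal tissue carried over would bring surface mucous, parietal and intestinal transcripts, but 9 such genes summed to 0.627 ± 0.0912 against 0.682 ± 0.322 CPM in MD4 and to 0.443 against 0.367 in INV3, a rise of 0.789% of that of the gastric genes at most, which argues against it. Sex is argued against as well, since 26 of the 27 joined calls were shared with the fit that had sex as a covariate. Sorting for tdTomato would remove unlabelled chief or neck cells, but carry-over of these past the gate stays open.

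The 61 genes called for caerulein in KrasG12D libraries came from 3 XX caerulein libraries against 1 XX and 2 XY saline libraries. Whether 1 caerulein library decides the calls stays open. Their median log2 change kept at least 98.5% of its value without each in turn, but calling the genes with all 3 holds it up by itself. Sex stays open, because in MD4 libraries the 56 autosomal genes differed between XX and XY in the direction of the calls by a median of 0.209, 23.02% of that in KrasG12D, which 4 of 216 labellings reached (exact permutation p = 0.0185, one-sided, the real one included). With sex as a covariate 8 calls were left, 6 of them among the 61 genes, whose median change was 0.960 (median SE 0.185) against 0.929 (0.181) without it, with every sign kept, while their median unadjusted p went from 9.86e-05 to 0.000491 and genes of all tested with an unadjusted p under 0.05 from 2161 to 1477. The number series also leaves 7 residual degrees of freedom (8 without it) and gave 612 calls, all 61 among them. It lowered the median SE to 0.171, so what the lost degree costs stays open.

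The 1372 calls among the saline splits point to a structure of the INV3 saline libraries, since they came from the split of mtS-1662, mtS-1663 and mktS-1669, which are XX with title numbers under 1700, against mtS-1729, mktS-1731 and mktS-1732, which are XY with later numbers. Higher in the first were 726 genes, such as Lars2 (1011 ± 351 against 257 ± 60.2 CPM, SD, n = 3 each), AY036118 (366 against 117) and mmu-mir-689-2 (57.6 against 16.4), which can collect ribosomal reads, Socs3 (149 against 63.8) and Zfp36 (200 against 91.7), 11 of 23 cell cycle genes (camera adjusted p = 2.66e-10) and 6 of 17 immediate early genes (0.000627), and higher in the second were 646, such as Clu (1477 ± 214 against 459 ± 52.0) and Prss3 (972 against 155), with 8 of 27 enzymes (7.36e-06) and, without calls, markers of islets (median log2 -1.23, 0.000421) and macrophages (-1.52, 0.00426), none of these lists passing with an estimated correlation (0.0759 for immediate early genes, 0.465 to 0.485 for the others). Sex is argued against as the whole cause, because in MD4 the median XX to XY difference of these genes was -0.0229 in the INV3 direction, a value that 108 of 216 labellings reached, while the share on sex chromosomes (3.06% of the 1372 and 3.22% of all tested) decides nothing. The number series stays open: the MD4 difference was -3.89% of that in INV3, but in WT caerulein libraries, where the single XY library has an early number, the median was -0.000364 with 49.9% of signs the same, so the genes followed neither there, on 1 library. RNA or library quality, a change in the mix of cells and other biological explanations stay open.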
